A study of Triticum aestivum with 80 samples.

How the data were processed

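RNA was sequenced from crowns of field-grown wheat at Saskatoon, sampled at 5 harvests from September to November of 2010 and of 2013, in Norstar, Manitou, a spring-habit line in Norstar background and a winter-habit line in Manitou background. Each of the 40 groups of line, harvest and year had 2 replicates, and each replicate pooled 40 to 60 plants. RNA was extracted with a plant RNA kit from Agilent and libraries were made with Illumina TruSeq RNA chemistry. Per the submitters' processing notes, STAR, Cufflinks, HTSeq and DESeq2 were used upstream; their versions and roles and the genome build are not given in the sources used here.

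The deposited table is named as normalised counts, but its values are on a log2 scale: 12.8% lie below 0, the highest is 15.68, and 18872 of 151690 features are at exactly 0 in all libraries. The authors' deposited values are therefore treated as log2 counts, scaled for library size and moderated in the form of the regularised logarithm of DESeq2; this form was inferred from the values. Such values pull features with few reads toward their mean, so folds of weakly expressed features are understated. Total reads per library cannot be taken from them, the depth is unknown, and no counting interval or lower limit is given. Table columns name the near-isogenic lines by codes, and these were assigned to the winter and spring line by the letter w or s at the end of the code. The deposited annotation gives the length of each feature in bases and its best database matches. Its Gene Ontology columns carry shifted headers, so terms were assigned by content. A chromosome was taken only from a protein match that names it at 99% identity or more, which gave 10416 features, of which 4716 were tested. Names were informative for 89339 features, and 22027 had no UniProt match.

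Features with a normalised count of at least 10 in at least 8 libraries were tested, 80258 in all. A mean was fitted for each of the 40 groups with limma 3.58.1 in R 4.3.3 (40 residual degrees of freedom), with moderated variances that follow a trend with expression. Contrasts were averages over lines, years or harvests: t5 against t1, winter against spring habit, Norstar against Manitou background, and the interactions of habit with background, habit with time, background with time and year with time. Each was also computed within years, line pairs and harvests. P-values were adjusted by the method of Benjamini and Hochberg, and a feature was called at an adjusted p under 0.05 and at least 2-fold change. These p-values measure the spread between 2 pooled replicates per group, not between fields or independent lines. On simulated data of the same size, between 90% and 100% of features changed by 1.2 on the log2 scale were called, all of those changed by 1.5, and no unchanged feature. At adjusted p alone, between 1 and 15 unchanged features passed. The simulation used independent normal noise, without correlation between features or mixed libraries, so it does not give error rates for the real data.

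Gene lists, 26 in number, were fixed from words in the annotation before the data were examined: dehydrins and LEA proteins, cold-regulated proteins, CBF/DREB factors, ice recrystallization and antifreeze, fructan, raffinose and galactinol, photosynthesis, histones and DNA replication, cyclins and mitosis, cytosolic ribosomal proteins, vernalization and photoperiod, MADS-box, circadian clock, heat shock and chaperones, pathogenesis-related, antioxidant enzymes, lipid desaturation and transfer, flavonoid synthesis, gibberellin, auxin, abscisic acid, cell wall, autophagy and senescence, and markers of floral organs, of roots and of organelle or rRNA transcripts. Word matches bring in members that do not do what the list's name says. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Gene Ontology terms with 10 to 500 tested features (3025 terms) were tested for over-representation by Fisher's exact test against 54299 tested features with a term.

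The named genes follow a rule set together with the lists. For t5 against t1, habit, background and habit by time these are, from each list, the called feature of largest change, and the 5 highest and 5 lowest called features with distinct informative names that had the same sign in both years and in the member comparisons. For the other interactions the 3 highest and 3 lowest were taken, and all matches to VRN1, VRN2, FT and vernalization proteins were followed as a group. Where the text names others, they were chosen after their values were seen.

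Alternatives tried were quantile normalisation, no filter, a mean of at least 20 normalised counts, no fold threshold, a replicate block within each year or harvest, robust variance moderation, each library left out in turn, 2013 without t4, and each year alone. Median centring and leaving out 10 libraries with markers of another line were added after seeing the data. Alternatives that need values on the count scale had been listed as well and were not run: pseudocounts of 0.5 and 5, TMM factors, and count-based tests on recovered reads. For other-line markers, features were taken whose lowest library on 1 side lay above the highest on the other over all libraries of 2010, by more than 2 on the log2 scale for backgrounds and by more than 1 for habits within a background. Each library's share is the median, on the linear scale, of its position between the mean levels of the 2 sides. Regroupings of libraries, 100 for each comparison, gave the counts that other groupings produce. Tables and plots used the R package data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.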

Results

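Transcript levels were measured in wheat crowns, the stem base from which a wheat plant regrows after winter, in plants that hardened in a field through autumn. The set comprised 80 libraries in 40 groups of 2, from 4 lines, 5 harvests (t1 to t5) and 2 years (2010 and 2013). Norstar (NO) has winter habit, so it needs a period of cold before it flowers, and Manitou (MA) has spring habit. The other lines were their near-isogenic counterparts, a spring-habit Norstar (SN) and a winter-habit Manitou (WM). Harvests in 2010 ran from 22 September (month 9) to 4 November (month 11), at 0, 12, 26, 33 and 43 days after the first, and those in 2013 came at 0, 14, 28, 28 and 40 days after 23 September. The labels give t3 and t4 of 2013 the same date, 21 October. Each replicate was a pool of 40 to 60 plants. The deposited values are on a log2 scale that had already been normalised and moderated, so the read depth behind each value is unknown, and no counting interval could be given. Library medians over the 80258 features tested lay between 5.63 and 5.80, and the median residual SD between replicates was 0.205 on the log2 scale. Correlations across features between the 2 libraries of a group (features are not independent replicates) ran from 0.954 in NO at t5 of 2013 to 0.994. Features are assembled loci named by their best database match, and the nearly identical copies of a gene on the A, B and D genomes can share reads, so the split between copies is uncertain for every gene named.

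Genetic background separated the libraries most. Differences between the Norstar background (NO and SN) and the Manitou background (WM and MA) made up 49.8% of the sum of squares across features, harvest 17.9%, year by harvest 10.1%, year 4.26% and habit 1.11%, against 6.07% between replicates. The first principal component held 51.1% of the variance and the second 15.4%.

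**Figure D1:**
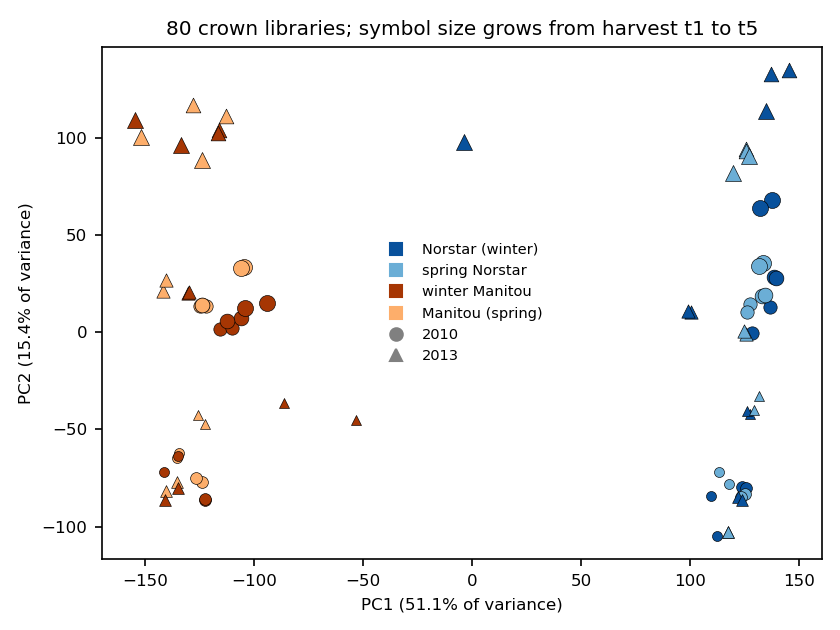
Scores of the 80 libraries on the first principal component (horizontal, 51.1% of variance) and the second (vertical, 15.4%), with line, year and harvest marked. Norstar-background and Manitou-background libraries fall on opposite sides of the first component, and a library of NO at t5 of 2013 lies between them.

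In 10 of the 40 libraries of 2013, features that mark another line were present above the highest share seen in 2010, which was 0.05. All libraries of NO, SN and WM at t1 were among them, as were both libraries of NO at t3, replicate 1 of NO at t5 and replicate 2 of SN at t5, and no MA library was. Shares were measured on 1447 features marking the Norstar background, 496 marking the Manitou background, and 6 to 9 habit markers for each line. Replicate 1 of NO at t1 carried a share of 0.73 of SN markers and 0.28 of its own, and replicate 1 of NO at t5 carried 0.61 of Manitou markers and 0.40 of its own. Because 6 of these libraries belong to t1, the totals and main lists of the comparisons of t5 with t1 are given below also without the 10 libraries, a setting chosen after seeing the data. Values for intervals, lines and single genes include them.

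**Figure D2:**
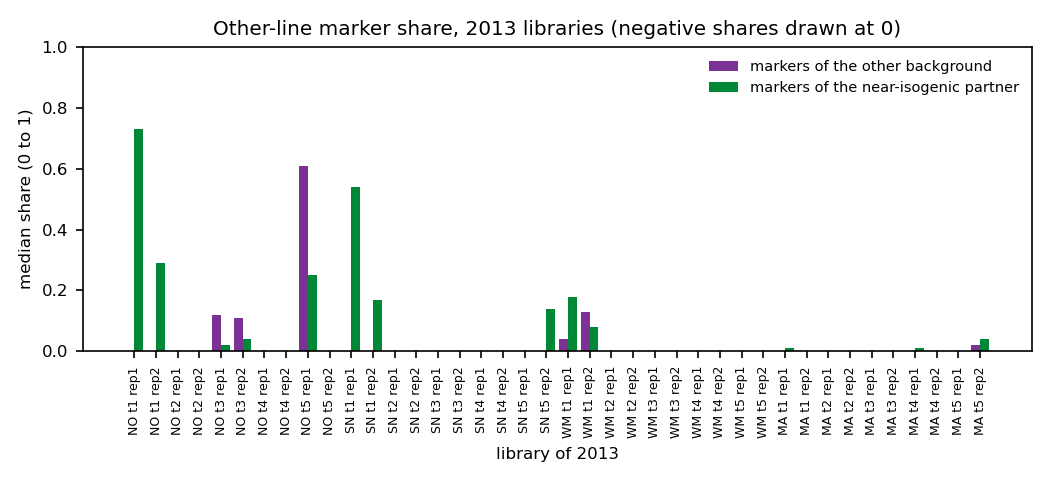
Share of markers of another line in each library of 2013, as a median share from 0 to 1 over the marker features. The highest bars are replicate 1 of NO at t1 (0.73) and replicate 1 of NO at t5 (0.61).

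The question of how the crown transcriptome changes as plants harden was addressed by comparing t5 with t1, over all lines and both years (16 libraries each). Transcripts of cold and dehydration protection rose. An unspecified dehydrin, a hydrophilic protein that protects cells during water loss, rose 38.4-fold (XLOC_120750, log2 5.26 ± 0.043 SE), from 7.22 ± 1.7 (SD, n = 16) to 12.49 ± 1.1 (SD, n = 16). Dehydrin DHN3 rose 31.6-fold (XLOC_125808, 4.98 ± 0.055), the barley low-temperature protein BLT14.1 29.5-fold (XLOC_027256, 4.88 ± 0.072), the wheat cold-responsive dehydrin CS66 23.9-fold (XLOC_132762, 4.58 ± 0.045), and the ABA-inducible LEA protein PHV A1 21.3-fold (XLOC_083168, 4.41 ± 0.046). Of 77 measured cold-regulated features, 60 rose and 2 fell, with a median log2 change of 1.84. Of 52 dehydrin and LEA features, 37 rose and none fell (limma, with 47 higher and 2 lower at an unadjusted p under 0.05), with a median of 1.60. Adjusted over the list alone, the counts were again 60 and 37. Both lists moved as groups (camera adjusted p = 2.9e-44 and 3.6e-31), and both calls held with an estimated correlation (adjusted p = 0.00031 for each). The lists overlap, with dehydrin XLOC_120750 for example in both, so they are not separate evidence. Within 2010 the cold-regulated list had 61 higher and 2 lower features and the dehydrin list 23 higher, within 2013 the numbers were 51 and 3 for the first list and 42 higher for the second, and without the 10 libraries they were 61 and 2, and 32 higher. In NO the median rise of the cold-regulated list was 2.46, in MA 1.89, in WM 1.76 and in SN 1.66.

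**Figure D3:**
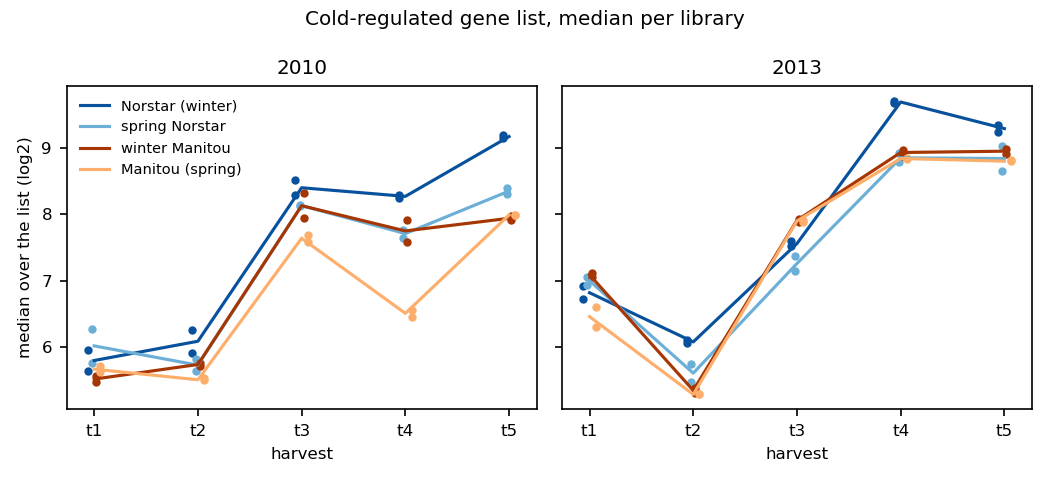
Median level of the 77 cold-regulated features (log2, vertical) at harvests t1 to t5 for the 4 lines, with 2010 and 2013 in separate panels. Lines join the means of 2 libraries, and points are single libraries. In 2010 NO reached 9.17 at t5 and MA 7.99, and in 2013 the level was already 8.80 to 9.29 at t5 after a low of 5.29 to 6.08 at t2.

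Transcripts of wounding and defence chemistry were among those that fell. A Bowman-Birk trypsin inhibitor fell 29.5-fold (XLOC_050201, -4.88 ± 0.073), a GDSL esterase/lipase 27.9-fold (XLOC_140260, -4.80 ± 0.080), linoleate 9S-lipoxygenase 1, which makes oxylipins, 26.5-fold (XLOC_090301, -4.73 ± 0.076), an inositol oxygenase 25.3-fold (XLOC_138179, -4.66 ± 0.061) and the Hessian-fly response protein Hfr-2 22.4-fold (XLOC_101272, -4.48 ± 0.070). The 47 fructan features split, with 4 higher and 10 lower; sucrose:sucrose 1-fructosyltransferase, which starts fructan synthesis, fell 6.02-fold (XLOC_149160, -2.59 ± 0.073) and by nearly equal amounts in each year (-2.60 and -2.58). Of 27 raffinose and galactinol features, 5 rose and 7 fell. Lower features also outnumbered higher ones among the antioxidant enzymes (15 against 2 of 262, with glutathione S-transferase 4, XLOC_094585, at -2.61 ± 0.072) and in the flavonoid list (28 against 10 of 265, with cinnamoyl-CoA reductase 1, XLOC_103760, at -2.63 ± 0.082). Expansin-B11, which loosens cell walls, fell 6.01-fold (XLOC_124374, -2.59 ± 0.070), although the cell wall list of 416 had 12 higher and 17 lower features.

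Photosynthesis transcripts moved in opposite directions in the 2 years. Of 173 such features, 41 rose and 8 fell in the mean over years, but in 2010 alone 122 rose and 4 fell (median 2.09) and in 2013 alone 69 fell and none rose (median -0.82). Without the 10 libraries, which leaves mainly 2010 in this comparison, 104 rose and 3 fell. The list's member of largest change was not an enzyme of photosynthesis but a chaperonin that binds RuBisCO, which fell 10.5-fold (XLOC_128061, -3.39 ± 0.069). Photosynthesis features also mark green tissue, and library medians of the list ran from 4.84 to 5.75 at t1 of 2010 and from 6.58 to 7.56 at t5.

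Defence proteins, lipid transfer proteins and growth genes changed in part. Of 242 pathogenesis-related features 32 rose and 21 fell, defensin Tm-AMP-D1.2 by 11.7-fold (XLOC_138857, 3.54 ± 0.063), and of 155 lipid features 19 rose and 3 fell, the lipid-transfer protein AKCS9 by 5.09-fold (XLOC_007051, 2.35 ± 0.093). Histones and DNA replication had 1 higher and 16 lower features of 418, cyclins and mitosis 2 and 3 of 452, and ribosomal proteins 1 and 5 of 908. The ribosomal member of largest change was a chloroplast protein, 30S ribosomal protein S7 (XLOC_109567, -1.50 ± 0.10). In the heat shock list of 285, 9 rose, among them heat stress transcription factor A-2c (XLOC_014559, 2.08 ± 0.048), and 20 fell. For abscisic acid 12 rose and 5 fell of 314, for gibberellin 7 and 1 of 77, for auxin 4 and 10 of 309, for autophagy and senescence 4 and 5 of 115, for CBF/DREB cold regulators none and 2 of 26 (limma, 7 higher and 14 lower at unadjusted p), and for ice recrystallization and antifreeze 1 and none of 41 (18 and 13 at unadjusted p). No feature of the 12 in the circadian list passed (limma, 3 higher and 6 lower at unadjusted p). Among markers of other tissues, 1 rose and 4 fell of 68 floral organ features, led by the sugar transporter SWEET17 (XLOC_103324, -1.54 ± 0.078), and 1 rose and 3 fell of 42 root features. Of 98 organelle-encoded and rRNA features, used as a sign of RNA quality, 1 rose and none fell (33 higher and 36 lower at unadjusted p). Adjusted over the list alone, none of these counts changed.

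Several of these counts moved without the 10 libraries, where t1 of 2013 rests on MA. The comparison then averages all 4 lines of 2010 with MA alone of 2013. Such shifts can therefore come from the greater weight of 2010 as well as from the libraries left out. Histones then had 15 higher and 5 lower features, ribosomal proteins 12 and 3, cyclins 5 and 5, heat shock 16 and 18, antioxidant enzymes 8 and 39, flavonoid synthesis 23 and 42, fructan 10 and 11, cell wall 25 and 19, the pathogenesis-related list 16 and 30, gibberellin 12 and 2, auxin 3 and 16, abscisic acid 12 and 10, and ice recrystallization none higher and 4 lower. Sizes of single changes differed between years as well: PHV A1 (XLOC_083168) rose by 5.93 in 2010 and 2.90 in 2013, heat stress factor A-2c (XLOC_014559) by 3.12 and 1.04, and AKCS9 (XLOC_007051) by 1.38 and 3.32, while glutathione S-transferase 4 (XLOC_094585) changed by -4.41 and -0.82 and SWEET17 (XLOC_103324) by -0.86 and -2.22.

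By the camera test with its preset correlation, 11 of the 26 lists passed for t5 against t1, 6 upward and 5 downward. Apart from the cold-regulated and dehydrin lists, all lost the call with an estimated correlation. The upward ones were photosynthesis (1.8e-08, adjusted p = 0.43 with an estimated correlation), pathogenesis-related (0.00039, then 0.43), lipid (0.012, then 0.46) and abscisic acid (0.044, then 0.40). The downward ones were ribosomal proteins (4.4e-07, then 0.46), histones (6.0e-06, then 0.46), antioxidant enzymes (7.8e-05, then 0.43), heat shock (0.043, then 0.46) and cyclins (0.043, then 0.46). In 2010 alone histones, ribosomal proteins and heat shock turned upward (camera adjusted p = 2.1e-07, 1.1e-07 and 0.0014). Cyclins also had the upward sign (0.18), and the pathogenesis-related and abscisic acid lists the downward sign (0.39 and 0.58), but these did not pass. For the fructan list the median was 0.10 and the mean -0.18, and for the root list they were 0.08 and -0.08.

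Gene Ontology terms among the risers were led by response to water (28 of 29 features against 0.533 expected by chance, adjusted p = 1.49e-44), followed by photosystem II (37 of 79, adjusted p = 1.05e-39), and included chlorophyll binding (38 of 88, adjusted p = 2.06e-39), response to stress (49 of 183, adjusted p = 2.06e-39) and light harvesting (28 of 43, adjusted p = 1.02e-35). Response to water had 22 higher features within 2010 and 26 within 2013, whereas photosystem II had 70 higher in 2010 and 25 lower in 2013. Chitinase activity (14 of 60, adjusted p = 9.16e-10) rested on 2013, with 28 higher there and 8 lower in 2010, and 1 was higher without the 10 libraries. Among fallers the terms included oxylipin biosynthesis (51 of 124, adjusted p = 2.9e-42), O-methyltransferases (39 of 95, adjusted p = 4.44e-32), biosynthesis of aromatic compounds (25 of 46, adjusted p = 5.15e-24), inhibitors of serine endopeptidases (33 of 97, adjusted p = 5.15e-24), response to wounding (35 of 323, adjusted p = 2.34e-09) and lignin biosynthesis (27 of 155, adjusted p = 1.39e-11). Oxylipin biosynthesis had 54 lower features in 2010 and 41 in 2013, and O-methyltransferases had 41 in each year.

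In total 1567 features were higher and 1973 lower at t5 (limma, adjusted p under 0.05 and at least 2-fold). The count was 8465 within 2010 and 8044 within 2013, and without the 10 libraries it was 5463, of which 2900 were shared with the set above. Across features the changes of the 2 years had a correlation of 0.0706, and of 2933 features called in both years 1507 changed the same way and 1426 the opposite way. By line, 3224 features were higher and 3358 lower in NO, 1724 and 1796 in SN, 1452 and 2980 in WM, and 1802 and 2214 in MA.

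Between successive harvests of 2010, the first interval was marked by decline, with 217 features higher and 2859 lower at t2 than at t1. From t2 to t3, 2099 rose and 1285 fell, from t3 to t4 280 and 282, and from t4 to t5 351 and 280. In 2013 the first interval had 1104 higher and 677 lower, t2 to t3 1526 and 1356, and t4 to t5 1604 and 794. Between t3 and t4 of 2013, harvests with the same labelled date, 1579 features were higher and 1936 lower at t4. Cold-regulated features went against the balance of the first interval in each year. Relative to t1, 8 were higher and 1 lower at t2 of 2010, and 58 higher and 1 lower at t3. In 2013 37 were lower and 1 higher at t2, 22 were higher at t3 and 58 at t4. The change from t2 to t3 correlated at 0.608 across features between years, with 1238 of 1251 features called in both years changing the same way.

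Winter and spring habit were compared within each background, NO with SN and WM with MA (40 libraries of each habit). Matches to the flowering regulator VRN1 differed between habits. The locus matching VRN-A1 (XLOC_090960, described as MADS-box transcription factor 14) was 1.38 ± 0.041 lower on the log2 scale in winter lines over all harvests, that is, a habit effect of -1.38. At t1 of 2010 it stood at 3.49 ± 0.019 (SD, n = 2) in NO and 3.54 ± 0.041 in WM, against 7.00 ± 0.011 in SN and 7.00 ± 0.26 in MA. The winter lines then rose, to 6.10 and 6.20 at t3 and to 7.39 and 7.00 at t5, when the difference between habits was -0.13 ± 0.13 (limma adjusted p = 0.64). In 2013 the winter lines were at 3.80 (NO) and 3.90 (WM) at t2 and at 8.12 and 8.13 at t5. At t1 of that year they were at 6.12 and 5.72, in libraries that carried markers of another line. Further MADS-box loci were lower in winter lines, namely another match to MADS-box transcription factor 14 (XLOC_105457, -1.76 ± 0.043), a locus matching VRN-B1 (XLOC_100830, -1.69 ± 0.051) and MADS-box transcription factor 18 (XLOC_033546, -2.05 ± 0.092). Unlike the VRN-A1 match, the VRN-B1 match was still lower in winter lines at t5, by -1.72 ± 0.16 in 2010 and -1.25 ± 0.16 in 2013. All 3 VRN1 matches rose from t1 to t5, by 1.84 ± 0.064, 3.31 ± 0.069 and 2.99 ± 0.081 in the order named.

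**Figure D4:**
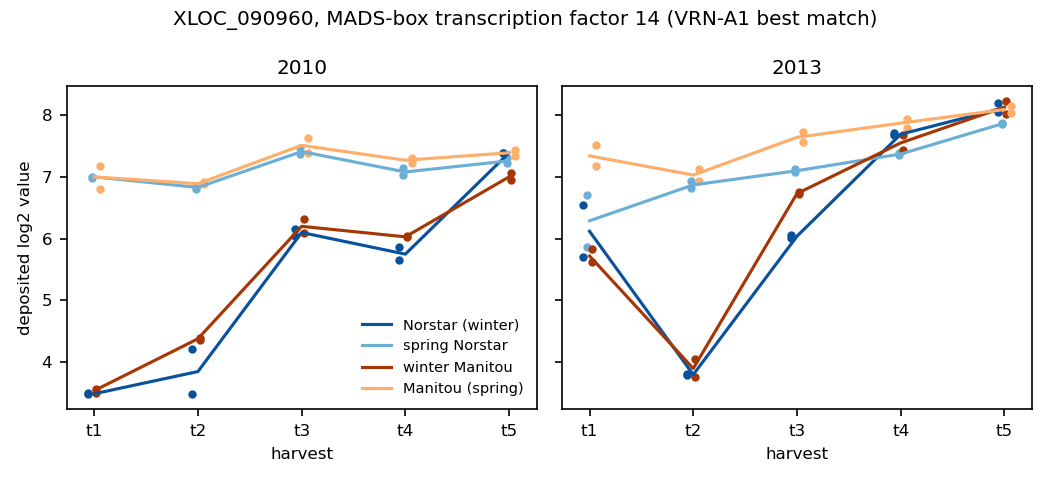
Level of the VRN-A1 match XLOC_090960 (log2, vertical) at harvests t1 to t5 in the 4 lines, with 2010 and 2013 in separate panels. Lines join the means of 2 libraries, and points are single libraries. At t1 of 2010 the winter lines stand at 3.49 and 3.54 and the spring lines at 7.00, and by t5 all 4 lie between 7.00 and 7.39.

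Of 82 MADS-box features 7 fell with winter habit and none rose (limma, 22 higher and 24 lower at an unadjusted p under 0.05), and of the 58 in the vernalization and photoperiod list 3 fell and none rose (19 higher and 8 lower at unadjusted p). Adjusted over the list alone, the counts were again 7 and 3. The vernalization list as a whole did not move (adjusted p = 0.23), its median being 0.04 and its mean -0.02. No match to FLOWERING LOCUS T, which carries the flowering signal, passed for habit in the mean over harvests (XLOC_028779, -0.06 ± 0.067, limma adjusted p = 0.63; XLOC_039747, 0.14 ± 0.056, limma adjusted p = 0.054; XLOC_096824, -0.05 ± 0.055). At single harvests XLOC_039747 differed by 0.86 at t2 of 2010, 0.65 at t2 of 2013 and -0.53 at t3 of 2013, and XLOC_028779 by -0.70 at t1 of 2010 (limma adjusted p = 0.0012, 0.025, 0.039 and 0.02). From t1 to t5 they changed by -1.74 ± 0.11 (XLOC_028779), -1.26 ± 0.088 (XLOC_039747) and -0.35 ± 0.088 (XLOC_096824). These loci were weakly expressed, so differences between habits and harvests may be understated. In NO of 2010 they stood at 3.83, 3.90 and 3.14 at t1 and at 1.68, 1.68 and 2.67 at t5, in the same order. Loci matching VIN3-like and OBERON-like proteins lay between -0.05 and 0.00 for habit.

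Beyond flowering genes, winter lines had 9.88-fold more polyubiquitin (XLOC_094117, 3.30 ± 0.076), 3.65-fold more of the RuBisCO-binding chaperonin beta subunit (XLOC_128061, 1.87 ± 0.043), 2.89-fold more Peroxidase 2 (XLOC_036530, 1.53 ± 0.055) and 2.42-fold more of a DnaJ co-chaperone (XLOC_094764, 1.27 ± 0.041). They had less histone H2B.1 (XLOC_109327, -2.39 ± 0.073), less of a binding partner of the cell-death regulator ACD11 (XLOC_092338, -2.40 ± 0.078) and less of a purple acid phosphatase (XLOC_072277, -1.79 ± 0.12). PIF1 helicase (XLOC_028224) was lower in WM than in MA (-4.06) and did not differ between NO and SN (-0.03). Sizes differed between the pairs in other genes too: BLT14 had 1.70 for NO and SN and 0.46 for WM and MA, MADS-box transcription factor 18 had -1.15 and -2.94, the chaperonin 1.25 and 2.48, and the phosphatase -1.12 and -2.47. The cold-regulated protein BLT14 was 2.12-fold higher (XLOC_023278, 1.08 ± 0.059), with nothing at t1 (0.09 ± 0.19 in 2010, -0.11 ± 0.19 in 2013) and 2.19 ± 0.19 and 1.53 ± 0.19 at t5; without t4 of 2013 the mean was 0.93. Cold-regulated features shifted upward together in winter lines, though by little. Their median was 0.27, 59 of 77 were higher and 1 lower at adjusted p alone, and 1 passed the 2-fold threshold (camera adjusted p = 2.9e-48, and 0.00025 with an estimated correlation). The dehydrin list (median 0.16, adjusted p = 6.0e-18, 0.010 with an estimated correlation), photosynthesis (0.12, 1.5e-18, 0.039) and pathogenesis-related features (0.08, 1.8e-13, 0.026) were shifted upward too. Heat shock (-0.04, 1.7e-07, 0.040) and the circadian list (-0.07, 0.00031, 0.010) were shifted downward. A further 8 lists passed only with the preset correlation: CBF/DREB (adjusted p = 0.058 with an estimated correlation), fructan (0.21), lipid (0.14), ice recrystallization, histones, cyclins and antioxidant enzymes (0.48 each) and ribosomal proteins (0.62). Protein refolding was the sole Gene Ontology term past the threshold among features higher in winter lines (3 of 45, adjusted p = 0.00154), and its 3 members were loci of that chaperonin subunit, called in each year.

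In total 40 features were higher and 37 lower in winter lines (limma). The pair NO and SN gave 96 called features, and WM and MA 208. Of 28 features called in both pairs 27 had the same sign, against 0.123 for independent lists. Within 2010 the count was 138 (91 higher and 47 lower) and within 2013 it was 69 (38 and 31), and the 57 called in both years all had the same sign. Without the 10 libraries it was 109 (52 and 57), of which 76 were shared. At individual harvests of 2010, from t1 to t5, 531, 61, 253, 461 and 383 features were higher and 108, 52, 212, 336 and 135 lower. In 2013 217, 120, 1108, 133 and 224 were higher and 50, 150, 164, 191 and 286 lower. The counts at t1, t3 and t5 of 2013 include libraries with markers of another line. Both NO libraries at t3, where 1108 were higher, carried Manitou markers (shares of 0.12 and 0.11). Counts of single harvests without these libraries are not given. Each habit contrast rests on a single near-isogenic line per background, so any other segment carried along with the habit locus is part of it.

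Norstar and Manitou backgrounds were compared within each habit, NO with WM and SN with MA. Transcripts of chromosome 6A, which carries genes of many unrelated functions, were lower as a block in the Manitou background. Of 211 features placed on 6A, 173 were higher in Norstar background and 1 lower, with a median log2 difference of 2.23. The call rate there was 82.5%, against 9.56% over all 4716 features with a chromosome (Fisher's exact test, odds ratio 71.5, adjusted p = 8.36e-152). Both arms showed it (2.21 on the short arm and 2.25 on the long arm), as did both line pairs (2.20 for NO and WM, 2.25 for SN and MA) and both years (2.26 and 2.22). Features of 6D were shifted the other way, with a median of -0.73, 88.4% of 249 below 0, and 29 lower and 8 higher by the 2-fold threshold. The third copy, 6B, had a median of 0.02, and all chromosomes other than 6A and 6D had a median of 0.03. A chromosome was assigned only where the database match named it at 99% identity or more, which held for few of the called features. Of 302 higher features with a chromosome 57.3% were on 6A, and of 149 lower ones 19.5% were on 6D.

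**Figure D5:**
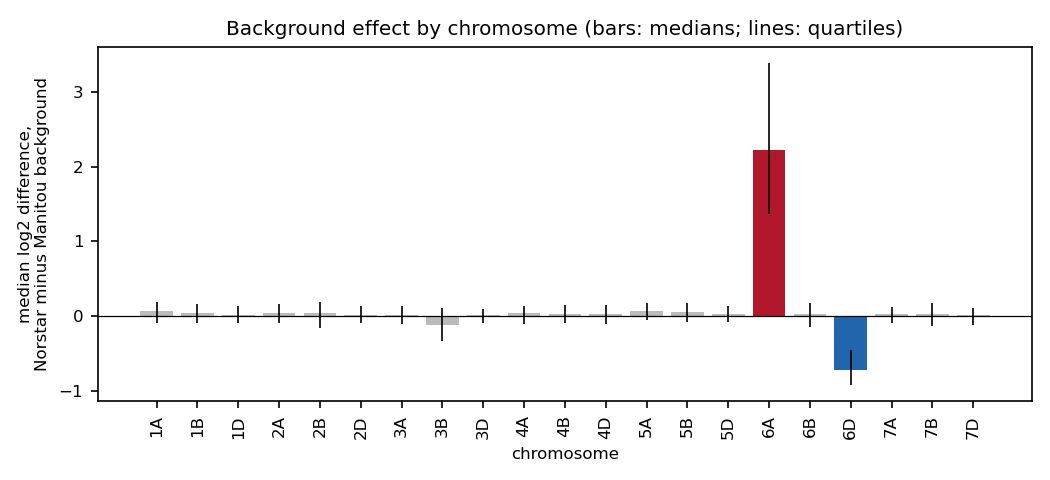
Median difference between Norstar and Manitou backgrounds (log2, vertical) for features of each chromosome, with lines spanning the quartiles. Chromosome 6A stands at 2.23 and 6D at -0.73, and the other chromosomes lie between -0.12 and 0.07.

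The largest single differences included housekeeping genes. Norstar-background lines had 201-fold more of a calnexin homologue (XLOC_115533, 7.65 ± 0.064), 126-fold more S-adenosylmethionine synthase (XLOC_116566, 6.98 ± 0.055), 120-fold more adenosine kinase 1 (XLOC_111953, 6.91 ± 0.061) and 113-fold more 60S ribosomal protein L6 (XLOC_113861, 6.82 ± 0.055), all with identifiers whose nearest neighbours with a known chromosome are on 6A on both sides. Manitou-background lines had more of the aluminium-induced protein wali5 (XLOC_012783, -6.75 ± 0.16), a disease resistance protein RGA3 (XLOC_003236, -6.67 ± 0.15), a GDSL esterase/lipase (XLOC_128015, -6.59 ± 0.11) and early nodulin-93 (XLOC_072310, -6.04 ± 0.17). Where a near-identical copy exists, a difference in sequence between cultivars can move reads between loci, so such folds do not separate expression from mapping.

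Cold-regulated genes differed between backgrounds as well. Of 77 cold-regulated features, 20 were higher in Norstar background and 2 lower (median 0.49), with 27 and 2 in 2010, 13 and 5 in 2013, and 23 and 2 without the 10 libraries. Dehydrin COR410, whose neighbours by identifier are on 6A, was 7.17-fold higher in Norstar background (XLOC_111607, 2.84 ± 0.042), and a CS66 locus between 6D neighbours was 18.1-fold lower (XLOC_123991, -4.18 ± 0.075). Of 52 dehydrin and LEA features 7 were higher and none lower (limma, 33 higher and 8 lower at adjusted p alone). The transcription factor dreb2 (XLOC_029311, 2.37 ± 0.054), a thaumatin-like protein (XLOC_030347, 2.38 ± 0.040), a sucrose:sucrose 1-fructosyltransferase (XLOC_135450, 3.19 ± 0.038) and galactinol synthase 2 (XLOC_032267, 2.37 ± 0.057) were each higher in Norstar background. The fructan list, however, had 4 higher and 4 lower features of 47 and the raffinose and galactinol list 2 higher and none lower of 27 (camera adjusted p = 0.98 for each). Also higher in Norstar background were the match to the Polycomb protein VERNALIZATION 2, which differs from the cereal repressor called VRN2 (XLOC_078177, 4.23 ± 0.052), MADS-box transcription factor 47 (XLOC_074337, 4.56 ± 0.060) and histone H2B.2, again between 6A neighbours (XLOC_115867, 6.44 ± 0.061). By camera, 4 lists passed, all upward and none with an estimated correlation: cold-regulated (9.8e-11, adjusted p = 0.58 with an estimated correlation), dehydrin (0.0035, then 0.93), histones (57 higher and 13 lower of 418; 2.0e-07, then 0.93) and ribosomal proteins (54 and 21 of 908; 0.0064, then 0.93). Adjusted over the list alone, their counts did not change. Gene Ontology terms among features higher in Manitou background included polysaccharide binding (40 of 183, adjusted p = 1.16e-15), cell surface receptor signalling (30 of 124, adjusted p = 7.94e-13), nodulation (19 of 63, adjusted p = 1.62e-09) and dhurrin biosynthesis, a cyanogenic glucoside pathway (8 of 17, adjusted p = 2.66e-05). Terms of transposon activity were enriched in both directions, DNA integration with 47 higher and 48 lower of 393.

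In total 4955 features were higher and 3423 lower in Norstar background (limma). Within years the counts were 8541 and 8426, and the 7800 features called in both all had the same sign. The 2 line pairs gave 8238 and 8862, with 7753 of the same sign in both.

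Whether the habit effect depended on background was tested as the difference between the NO and SN effect and the WM and MA effect. A syntaxin-binding protein (XLOC_031521, 5.61 ± 0.21), the disease resistance protein RPM1 (XLOC_090802, 4.13 ± 0.17) and PIF1 helicase (XLOC_028224, 4.03 ± 0.17) had a more positive winter effect in Norstar background. A SINA-like ubiquitin ligase (XLOC_070647, -3.10 ± 0.10), the kinase WNK9 (XLOC_092292, -2.44 ± 0.12) and nicalin (XLOC_089952, -2.41 ± 0.10) had a more negative one. RPM1, WNK9 and nicalin have identifiers within 4000 of the VRN-A1 match XLOC_090960. A segment carried along with the habit allele may therefore be part of their differences, which was not tested. In total 116 features were higher and 72 lower (limma), in a fit of 2010 alone 149 and 129, and in a fit of 2013 alone 255 and 110. The excess of higher calls was absent without the 10 libraries (157 and 157) and at a mean of at least 20 normalised counts (41 and 45).

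Whether winter lines changed more over the autumn than spring lines was tested as the difference between habits in the change from t1 to t5. Some protective proteins rose further in the mean over winter lines, dehydrin DHN4 (XLOC_124049) by 1.89 ± 0.20, with rises of 5.12 in winter and 3.23 in spring lines, and BLT14 (XLOC_023278) by 1.87 ± 0.19. The Norstar pair differed more: DHN4 rose by 5.87 in NO and 2.76 in SN, but by 4.37 in WM and 3.70 in MA. For BLT14 the rises were 5.28 and 2.77, against 2.59 and 1.36. A class I small heat shock protein (XLOC_066836) differed by 1.87 ± 0.20, having fallen in spring lines (-2.06) and hardly changed in winter lines (-0.19), though in 2013 alone the difference was 1.01 with limma adjusted p = 0.059. A sucrose:sucrose 1-fructosyltransferase (XLOC_133261) differed by 1.27 ± 0.21, with 1.08 in winter and -0.19 in spring lines. The VRN-A1 match (XLOC_090960, 2.19 ± 0.13) and a MADS-box protein of the AGL8 type (XLOC_110075, 2.53 ± 0.13) also rose further in winter lines, by 3.35 and 3.79 in 2010 and by 1.04 and 1.27 in 2013. The RuBisCO-binding chaperonin (XLOC_128061) differed by 2.06 ± 0.14, having fallen less in winter lines. Genes with a more negative change in winter lines included the transporter DETOXIFICATION 16 (XLOC_140043, -2.64 ± 0.16), a UDP-glycosyltransferase (XLOC_043608, -2.49 ± 0.18), bisdemethoxycurcumin synthase (XLOC_071613, -2.24 ± 0.22) and an auxin glucosyltransferase (XLOC_110377, -2.21 ± 0.18).

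Of 52 dehydrin and LEA features 9 had a more positive change in winter lines and none a more negative one (limma, 28 higher and 2 lower at adjusted p alone, and camera adjusted p = 1.3e-22, 0.0054 with an estimated correlation). In 2010 there were 21, and in 2013 5 against 2 lower. Without the 10 libraries the interaction rests on 2010 alone by construction, so the 21 found there are no separate check. Of 77 cold-regulated features 5 had a more positive change (4.2e-15, 0.043 with an estimated correlation), but the list's median was 0.61 in 2010 and -0.09 in 2013. The heat shock list (8 higher and 1 lower of 285; 5.6e-13, 0.0085 with an estimated correlation), photosynthesis (3 higher of 173; 4.4e-20, 0.036) and fructan (3 and 3 of 47; 0.00012, 0.025) were shifted upward. In 2010 alone 29 heat shock features and 32 photosynthesis features were higher and none lower at 2-fold, and in 2013 alone 2 and 1 were higher and 7 of each lower. Raffinose (0.0056, adjusted p = 0.24 with an estimated correlation) and lipid (0.0056, then 0.51) were upward, and flavonoid synthesis (1 higher and 10 lower of 265; 0.039, then 0.58) downward, only with the preset correlation. Adjusted over the list alone, these counts did not change. Response to water was again the leading Gene Ontology term (9 of 29, adjusted p = 5.43e-15, with 15 in 2010 and 5 in 2013), followed by response to stress (11 of 183, adjusted p = 8.69e-11). Some of its called members hardly differed between WM and MA, with rises of 1.88 and 1.97 for CS66 XLOC_123991 and 1.54 and 1.44 for DHN3 XLOC_124738. Another DHN3 locus did differ there (XLOC_117648, 3.93 and 2.57). The lower side included oxylipin biosynthesis (12 of 124, adjusted p = 1.21e-08; 12 in 2010 and 17 in 2013), transfer of hexosyl groups (10 of 148, adjusted p = 1.3e-05) and response to wounding (12 of 323, adjusted p = 0.000217; 17 in each year). In total 135 features were higher and 339 lower (limma). Within 2010 the split was 684 and 702 and within 2013 163 and 1362, and of 148 features called in both years 132 had the same sign. Without the 10 libraries, which again leaves 2010 alone, the split was 685 and 717.

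Changes over autumn also differed between backgrounds. REVEILLE 7, of a family of clock-related MYB factors (XLOC_030695, 3.94 ± 0.19), tyrosine/DOPA decarboxylase 1 (XLOC_018333, 3.92 ± 0.15) and glutathione S-transferase GSTU6 (XLOC_001897, 3.27 ± 0.23) had a more positive change in Norstar background. A Bowman-Birk inhibitor (XLOC_058528, -4.69 ± 0.15), Peroxidase 12 (XLOC_031006, -3.10 ± 0.20) and Peroxidase 2 (XLOC_018995, -2.92 ± 0.16) had a more negative one. In total 754 features were higher and 218 lower (limma), 1885 and 1242 in 2010, and 1149 and 405 in 2013. Without the 10 libraries, which leaves 2010 alone for this interaction, the split was 1898 and 1247. Of 100 regroupings of the libraries, 11 gave as many, the real one included. These regroupings carry the background difference itself into the interaction, so they cannot decide.

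The 2 autumns differed in how transcripts changed from t1 to t5. Cinnamoyl-CoA reductase 1 (XLOC_123839, 8.05 ± 0.33), non-symbiotic hemoglobin, which binds oxygen tightly (XLOC_083790, 7.19 ± 0.29), and early nodulin-93 (XLOC_149987, 6.28 ± 0.24) had a more positive change in 2013. Enzymes of carbon fixation and light capture had a more negative one, namely phosphoribulokinase (XLOC_125870, -6.75 ± 0.19), the small chain of RuBisCO (XLOC_035158, -6.47 ± 0.17) and a chlorophyll a-b binding protein (XLOC_127938, -6.45 ± 0.17). In total 7279 features were higher and 7118 lower (limma), and without the 10 libraries, where MA alone has both harvests complete in both years, the total was 16242. Year and habit interacted in few features over all harvests, with 13 lower and none higher (limma, 6600 higher and 8795 lower at an unadjusted p under 0.05). Weather, soil and sampling differ between years together, so a year difference here has no further attribution.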

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

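Apart from the regroupings of libraries, the year by time comparison behind the year differences for t5 against t1, the test of mixed plants in MA and the leaf-share covariate, the tests reported here were chosen only after the result was seen.

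Named genes whose effect differed between years by at least 1, by a limma test of the difference itself, are given first, as 2013 minus 2010 on the log2 scale. For t5 against t1, dehydrin XLOC_120750 (-1.20), DHN3 (-1.48), CS66 XLOC_132762 (-2.33) and PHV A1 (-3.02) rose less in 2013. The change was lower in 2013 also for heat stress factor A-2c (-2.08), an rRNA methyltransferase (-1.08), histone H2AXb (-1.25), SWEET17 (-1.36) and a peptide/nitrate transporter (-2.67). It was higher in 2013 for DREB1B (1.22), a thaumatin-like protein (1.97), galactosyltransferase 6 (1.17), the RuBisCO-binding chaperonin (1.92), glutathione S-transferase 4 (3.59), AKCS9 (1.94), a gibberellin 2-oxidase (1.60), IAA18 (1.97), protein phosphatase 2C 8 (1.71), DIN1 (1.56), 9S-lipoxygenase (1.59) and inositol oxygenase (1.13). The habit effect of the ubiquitin ligase SINAT5 (-1.44) and the background effect of a GDSL esterase/lipase (1.16) differed too. For habit by time the differences were negative for the VRN-A1 match XLOC_090960 (-2.31), AGL8 (-2.53), histone H2A (-1.65), a class I small heat shock protein (-1.72), auxin response factor 6 (-1.86) and release factor 1-2 (-1.29). They were positive for DETOXIFICATION 16 (2.49), bisdemethoxycurcumin synthase (2.38), PRB1-3 (1.76), ubiquitin-ribosomal protein L40-1 (1.49) and the auxin glucosyltransferase (1.30). Smaller differences passed too, among others for t5 against t1 in Hfr-2 (-0.92) and BLT14.1 (XLOC_027256, 0.45, a larger rise in 2013), for habit in MADS-box transcription factor 14 (XLOC_105457, 0.74), the ACD11 partner (0.72) and histone H2B.1 (0.54), and for background in CS66 XLOC_123991 (-0.88), COR410 (-0.51) and histone H2B.2 (-0.51). Values for t5 against t1 and for habit by time rest on t1 of 2013, where libraries of 3 lines carried markers of another line.

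Chromosome 6A features were lower, and 6D features higher, in the Manitou background. A loss of 6A with doubled copies of 6D in Manitou-background plants would shift 6D by -1, and the 6D median was -0.73 over all features and -0.89 (quartiles -0.94 to -0.74) in those with a mean of at least 8, so this stays open. Sequence differences that move 6A reads to both other copies alike would raise 6B as well as 6D, but the 6B median was 0.75 above that of 6D. Reads that moved mainly to 6D are not excluded by this comparison, so an effect of mapping stays open. The authors' normalisation would shift other chromosomes, and the median farthest from 0 among groups 1 to 5 and 7 was -0.12, on 3B with 9 features. Replacement of 6A by another chromosome whose reads are counted on 6D should spread the 6D shifts more than those of 6B, and stays open, with quartile ranges of 0.47 and 0.33 over all features but 0.20 and 0.18 at a mean of at least 8 (Fligner-Killeen p = 0.86, n = 41 and n = 21 features); copy number was not measured here.

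In 10 libraries of 2013 markers of another line were present, and in 9 of the 10 the own and the other shares added up to between 0.8 and 1.2, which is consistent with pools that held plants of more than 1 line. An exchange of whole libraries would give a share near 1, and the highest was 0.73. A change of the markers with harvest or year would show in both replicates, and it is argued against for the 2 libraries of NO and SN at t5, whose other replicates had a share of at most 0. For the other 8, where both replicates were affected, it stays open, the shares of replicates differing by up to 0.44. Whether seed, plots or tissue were mixed, or RNA or libraries at a later step, was not tested.

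Changes from t1 to t5 were nearly uncorrelated between the years. Mixed plants do not account for this alone, since MA, with no such library, had a correlation across features of 0.0406 between years. An exchange of t1 and t2 in 2013 was examined on deviations, each feature's level minus its mean over all harvests of the same year. On these, t2 of 2013 correlated better with t2 than with t1 of 2010 in all 4 lines (0.688 and 0.479 over lines). But so did t1 of 2013 (0.354 and -0.115), and in 0 lines did both harvests match their own best. The exchange therefore stays open. With the photosynthesis median as covariate the year by time count was 2333, but the median SE rose from 0.147 to 0.831, so that test is void and a different share of leaf tissue could still contribute. Weather before t1, which the design names only as year, stays open and untested.

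Regroupings were used to ask whether other groupings of the same libraries give as many calls. The real grouping was the 1 of 100 that gave as many for t5 against t1 (3540, highest other 733), habit (77, highest other 2) and background (8378, highest other 1673). So it was for habit by background (188, highest other 131), habit by time (474, highest other 402) and year by time (14397, highest other 7048). Regroupings split replicate pairs and put group differences into the residual spread, which can lower the other counts. In habit by time and year by time they also carry the habit or year difference itself into the interaction. Differences between plots, pools or single lines are not covered, so chance of that kind is not excluded. For background by time the regroupings cannot decide, and chance is not excluded: the real count was 972, the highest other 11978, and 11 of 100 groupings gave as many. Regrouping there exchanged lines of different background at t1 and t5, which carries the background difference itself into this interaction and can give such high counts.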

How the results depend on the processing

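Leaving out the 10 libraries and median centring were chosen only after the result was seen; the other alternatives were planned. The planned pseudocounts, TMM factors and count-based tests were not run, because the deposited values are already logarithms. Counts stayed within 1.5 times under quantile normalisation, median centring, no filter, robust moderation and without t4 of 2013. With each library left out in turn they ranged from 3481 to 3675 for t5 against t1, 73 to 82 for habit, 8224 to 8544 for background, 181 to 219 for habit by background, 403 to 641 for habit by time, 932 to 1107 for background by time and 13645 to 15511 for year by time; the library left alone in a group is assumed to vary like the other groups. Most of these extremes came from leaving out a library of NO at t5 of 2013. Named genes kept their direction in all fits; 25 results were no longer past the threshold under other alternatives and 37 with a library left out.

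A mean of at least 20 normalised counts, which tests fewer features, gave 4278 for background, 86 for habit by background, 295 for habit by time and 498 for background by time. Without a fold threshold the counts were 53295, 17669, 52281, 16363, 7684, 10446 and 49951 in the order above, since small changes then count.

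In 2010 alone the counts were 8465 for t5 against t1, 138 for habit, 1402 for habit by time and 3144 for background by time, with 14 lists past the threshold for habit by time. In 2013 alone they were 8043 for t5 against t1, 365 for habit by background and 1364 for habit by time, with 6 lists for habit. Without the 10 libraries they were 5463, 314 for habit by background, 1402 for habit by time and 3145 for background by time, with 15 lists for habit by time; the interactions with time then rest on 2010 by construction. With an estimated correlation 2 lists passed for t5 against t1, 6 for habit, 0 for background (camera; 4 with the preset correlation) and 5 for habit by time.

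Directions of some lists reversed, and the cause was not tested. For t5 against t1 in 2010 alone these were histones (adjusted p = 2.1e-07), ribosomal proteins (1.1e-07), heat shock (0.0014), cyclins (0.18), pathogenesis-related (0.39) and abscisic acid (0.58), and without the 10 libraries histones (0.22), cyclins (0.76), ribosomal proteins (0.13) and heat shock (0.50). In 2013 alone photosynthesis reversed for t5 against t1 (1.5e-19), ice recrystallization (0.88), cyclins (0.90) and antioxidant enzymes (0.90) for habit, and cold-regulated (0.10) and lipid (0.48) for habit by time.

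A replicate block within each harvest gave 3540, 77, 8378, 188, 475, 973 and 14398. Replicate numbers did not pair libraries: over 60 pairs of lines in a harvest the median correlation of replicate differences was 0.0231, from -0.426 to 0.186. Depth is unknown, so what it limits could not be assessed.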

Other observations

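The tests reported in this part were all chosen only after the result was seen. Several further groups of genes changed the same way from t1 to t5 in both years. Enzymes that release phosphate from membrane lipid breakdown products fell, with 9 of 11 features of phosphate homeostasis lower, 10 in 2010 and 8 in 2013 (adjusted p = 1.39e-10 for the term). Among them were the glycerophosphodiester phosphodiesterases GDPD1 (XLOC_048262, -3.72 ± 0.060) and GDPD2 (XLOC_020347, -3.57 ± 0.088). Asparagine synthetase, which makes a nitrogen storage amino acid, fell in 9 of 20 features, 8 in 2010 and 10 in 2013 (adjusted p = 2.25e-07), led by XLOC_083943 (-3.36 ± 0.061). Allene oxide synthase, an early step of jasmonate synthesis, fell in 7 of 10 features (adjusted p = 2.4e-07), as for XLOC_074959 (-1.90 in 2010 and -3.94 in 2013). Leucine breakdown fell in 10 of 15 features (adjusted p = 1.81e-10), although 3 were lower in 2013 alone.

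Some peptide receptor features rose, among them loci named as a receptor of the peptide hormone phytosulfokine, which acts in growth and defence. The peptide receptor term had 15 of 45 features higher, 10 in 2010 and 20 in 2013 (adjusted p = 5.77e-13), including phytosulfokine receptor 2 (XLOC_099804, 3.09 ± 0.077, and XLOC_097985, 2.81 ± 0.064). Loci named as the histone demethylase JMJD5, whose relatives take part in clock and chromatin regulation, rose in 9 of 12 features, 9 in 2010 and 8 in 2013 (adjusted p = 1.46e-11), led by XLOC_133681 (2.46 ± 0.073). In habit by time, oxalate oxidases, enzymes of the cell wall that release hydrogen peroxide, had a more negative change in winter lines in 4 of 14 features (adjusted p = 0.000463). In the mean over winter lines these 4 fell by -0.93 to -1.98, and in the mean over spring lines they changed by -0.78 to 0.18. Not all fell in both winter lines: XLOC_080770 changed by -1.71 in NO and by -0.15 in WM. For XLOC_080609 the changes were -2.82 in NO and -0.81 in SN, but -1.15 in WM and -0.75 in MA.

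Features called for habit lay near the VRN-A1 match more often than elsewhere. Within 4000 identifiers of XLOC_090960, 17 of 4439 features were called, against 60 of 75819 outside (Fisher's exact test, odds ratio 4.85, p = 8.3e-07), 8 of them higher and 9 lower in winter lines. Of 240 features with a chromosome in the window, 154 were on 5A. Polyubiquitin XLOC_094117, the ACD11 partner XLOC_092338 and the DnaJ co-chaperone XLOC_094764, named above for habit, lay in the window as well. By line pair, 16 of 96 called features lay in the window for NO and SN (odds ratio 3.42) and 25 of 208 for WM and MA (odds ratio 2.34). A linked segment carried along with the habit allele could do this and stays open, as the odds ratio of 2.34 lies between the bounds of 2 and 3 set for it. Identifier order is a rough stand-in for position, since 86.8% of successive features with a chromosome shared it.

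Across features, the change from t2 to t5 had a correlation of 0.628 between years, while that from t1 to t5 had 0.0706. Harvests were also compared by deviations, that is, each feature's level minus its mean over all harvests of the same year. Deviations at t1 of 2010 had a correlation of 0.479 with those at t2 of 2013 and of -0.115 with those at t1 of 2013. Deviations at t2 of 2010 had 0.688 and 0.354. These values compare patterns within each autumn, not expression levels.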
